A study of Ovis aries with 6 samples.

How the data were processed

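RNA from the somatic cells of sheep milk was sequenced in 6 libraries, 3 from a control diet and 3 from a diet with extruded linseed. Per the labels' protocols, 3 Comisana ewes at day 90 of lactation were fed hay and concentrate for 3 weeks, and the same ewes then received a concentrate with 20% extruded linseed on a dry matter basis for 3 weeks. Cells were pelleted from 250 ml of milk, and libraries were made with the TruSeq RNA kit and read on a HiSeq2000. The labels carry no field for diet: samples were placed in groups by the letter in their title, read with the series design, which names the 2 diets. The same animal identifier stood under the same number in both groups.

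The authors deposited 1 table of RPKM values (reads per kilobase of transcript, scaled to library size) for 49705 RefSeq transcripts, with a column for each library. Reads were trimmed with Trimmomatic 0.33, per the submitters' processing notes. The aligner, the genome build and the counting tool are not given in the sources used here. The table was used as RPKM, and DESeq2, set aside for a table of raw counts, was not run. An RPKM value is set by transcript length, so transcripts that share reads with another transcript of the gene or with a paralog depend on how the authors divided those reads.

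The low RPKM values stood at whole multiples of the value of 1 read, and the library totals and transcript lengths were solved from these steps, with a tolerance of 0.002 reads. The totals came to 22644050, 8805705 and 10602801 reads for control sheep 1, 2 and 3 and to 4941935, 5978026 and 19912996 reads for linseed sheep 1, 2 and 3, and the deepest library held 4.58 times the reads of the shallowest. The recovered reads summed to between 99.43% and 99.82% of these totals. In simulated RPKM values, 99.12% of 21232 transcripts with at least 100 reads came back exactly in every library. At a length of 2000 nt, 1 read was worth 0.0221 RPKM in the deepest library and 0.101 RPKM in the shallowest. A tested transcript had a median of 860 reads over the 6 libraries, and 574 of those tested had under 100.

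Gene symbols came from a RefSeq gene table of assembly ARS-UI_Ramb_v3.0, which is not shown to be the authors' build and was used for names alone. Accessions were matched without their version: 15836 of 49705 transcripts (31.9%) matched, to 11285 symbols, and 964 matched with the version as well. Transcripts with a mean of at least 1 RPKM over the 6 libraries were tested, 15891 in all, of which 7294 had a symbol, from 5976 genes. Several genes of the fixed lists, FASN and SREBF1 among them, were not matched and are not analysed here.

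Values were taken as log2(RPKM + 1), so a log2 change is on that scale and understates the change of low transcripts. The groups were compared with limma 3.58.1 in R 4.3.3 (a mean-variance trend and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 called). The fit without a block was chosen before the data were examined, as were the gene lists, the rule for named genes and the first set of other settings, the sheep as a block among them. The same animals gave both groups, and the deviations of the paired libraries from their group means correlated at 0.18, 0.25 and 0.40 across transcripts in sheep 1, 2 and 3. Control sheep 1 correlated more with linseed sheep 2 (0.24) than with its own linseed library, so the pairing rests on the animal identifiers, and the blocked value is given where it changes a call. The fit without the block leaves 4 residual degrees of freedom and the blocked fit 2. A standard error (SE) printed beside a log2 change is that of the fit without the block unless the block is named with it.

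The named genes were, in each direction, up to 12 genes of smallest p among those that passed and moved alike in all 3 sheep, or, where fewer passed, the genes of smallest p up to 8 in all. To these were added up to 4 members of smallest p in each list, a fixed set of lipid and milk genes, and the 10 most abundant transcripts of each group. Some genes that the rule takes are not reported here. The 28 lists covered milk proteins, mammary epithelium, lactose synthesis, prolactin signalling, involution, lipid and cholesterol metabolism, oxylipins, antioxidants, immune and stromal cell types, cytokines, interferon, stress, the cell cycle, ribosomal proteins, mitochondrial transcripts and erythrocytes. Each gene entered by its most abundant transcript. A p adjusted over the list alone was not corrected for the number of lists. Genes said to pass that way without the block did not pass over all transcripts in that fit. The 25 lists with at least 5 measured members were tested with camera of limma at a preset inter-gene correlation of 0.01, with the estimated correlation and fry as checks. The share of RPKM in milk protein genes was compared with a two-sided exact permutation test, whose smallest p is 0.1 over 10 splits of 3 against 3. Sign flips of the 3 within-sheep differences cannot give a two-sided p below 0.25.

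The fits were tested on simulated data for 15891 transcripts, with 200 changed by known amounts and with the spread of the blocked fit. At a log2 change of 1, 2 and 4, the fit without the block called 0 of 68, 0 of 66 and 19 of 66 changed transcripts, with 0 false calls. The blocked fit called 1, 16 and 52 of them, with 4 false calls. The simulated noise was drawn independently for each transcript and library. These false calls therefore do not measure the error of the blocked fit where transcripts vary together. The first set of other settings held other pseudocounts, filters and scalings, the block, fits without the trend or with array weights, and fits without each library or each sheep. Chosen after seeing the data were limma-voom on the recovered reads, a correction for transcript length, the block together with other settings, and summed transcripts per gene. For a test of depth, also chosen then, the recovered reads of each library were thinned at random (seed 23) to the total of the shallowest library, and the correlation of log2 change with length was taken again. Python 3.11.15 with matplotlib 3.10.9 recovered the reads and drew the plots.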

Results

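The data describe the transcripts of milk somatic cells, the epithelial and immune cells shed into milk, in 3 ewes before and after a linseed supplement rich in alpha-linolenic acid. There were 3 control and 3 linseed libraries, with 4941935 to 22644050 reads each as solved from the RPKM values. Linseed libraries of sheep 1 and 2 were shallower than their control libraries, and that of sheep 3 was deeper. Every ewe received linseed second, so the diet cannot be separated from the time between samplings. Across tested transcripts, control libraries correlated at 0.71 to 0.84 with one another and linseed libraries at 0.78 to 0.93.

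By mean RPKM, the most abundant transcripts of the control group were those of the caseins, the main milk proteins, led by kappa-casein (CSN3, NM_001009378.1) at a mean of 83000 ± 68130 RPKM (SD, n = 3) and beta-casein (CSN2, NM_001009373.1) at 66220 ± 55990. This order did not hold in control sheep 3, where PAEP had 9885 and CSN3 8902 RPKM. With linseed, the whey protein beta-lactoglobulin (PAEP, NM_001009366.1) ranked first, at 137800 ± 131800 RPKM against 41760 ± 28380 in controls. Ferritin heavy chain (FTH1), an iron storage protein, ranked 7 in controls at 7941 ± 2702 RPKM and 3 with linseed at 20680 ± 9139. Ferritin light chain (FTL) had 3407 ± 1724 and 8620 ± 1796 RPKM. The ribosomal protein gene RPLP1 was among the 10 most abundant transcripts of the linseed group and not of the control group, at 7970 ± 3439 RPKM with linseed. These are values without a test of rank.

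Caseins were lower with linseed in each of the 3 sheep, while the whey proteins were not. The log2 changes were -2.52 ± 1.01 (SE) for alpha-S1-casein (CSN1S1), -2.16 ± 0.97 for alpha-S2-casein (CSN1S2), -1.87 ± 1.12 for CSN2 and -1.82 ± 1.24 for CSN3, and none passed limma's adjusted p of 0.05. The value of CSN1S1 was that of its most abundant transcript, XM_012179357.2; the other, NM_001009795.1, had -1.38 ± 1.23. PAEP changed by 2.06, 1.46 and -1.09 on the log2 scale in sheep 1, 2 and 3, and alpha-lactalbumin (LALBA), a subunit of lactose synthase, by 1.29, 0.46 and -0.58. The sign of the mean change of LALBA, 0.39 ± 1.29, turned with quantile normalization (-0.23) and when milk proteins were left out of the total (-0.22). It also turned with the length correction (-0.165) and without control sheep 3 (-0.68), linseed sheep 1 (-0.22), linseed sheep 2 (-0.56) or sheep 1 (-0.06). Of the 11 measured milk protein genes, 7 were lower in all 3 sheep and 0 higher, among them butyrophilin (BTN1A1, -1.65 ± 0.78) and MUC15 (-1.71 ± 0.83) of the milk fat globule membrane. The count of calls in this list was 0 over all transcripts and 0 adjusted over the list alone. With the sheep as a block it was 0 over all and 8 adjusted over the list alone. The list had an adjusted p of 0.103 by camera of limma, 0.0543 with the block and 0.898 with an estimated correlation, and 0.131 after a length correction, or 0.00294 with the block as well.

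**Figure D1:**
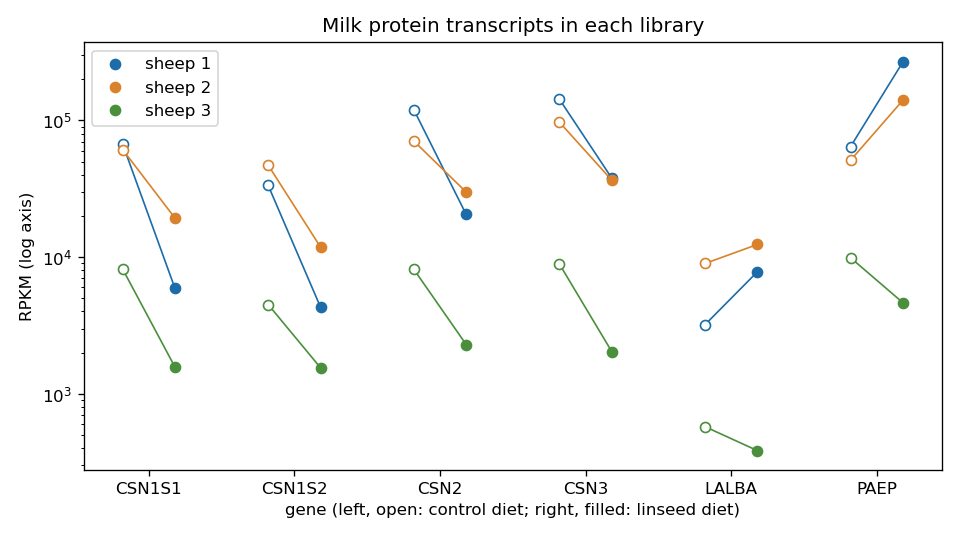
RPKM (log axis) of the 4 caseins, LALBA and PAEP in each library, with a line joining the control value (open point) and the linseed value (filled point) of each sheep. The linseed value lies below the control value for the 4 caseins in all 3 sheep, while PAEP and LALBA are higher in sheep 1 and 2 and lower in sheep 3.

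Milk protein genes took 36.2% ± 25.9 (SD, n = 3) of all RPKM in control libraries and 22.1% ± 17.3 in linseed libraries, a difference smaller than the spread between sheep (two-sided exact permutation p = 0.4). The share was 59.3%, 41.1% and 8.26% in control sheep 1, 2 and 3 and 34.9%, 28.9% and 2.39% with linseed, lower in each sheep (exact sign-flip p = 0.25, the smallest it can give). Caseins alone took 29.1% ± 21.9 and 6.64% ± 5.13 (exact permutation p = 0.3), and PAEP 5.16% ± 3.13 and 13.8% ± 12.5 (exact permutation p = 0.4). Sheep 3 had the lowest share under both diets. The difference of -14.2 percentage points was -2.65 without control sheep 1 and -4.35 without linseed sheep 3.

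No transcript passed the threshold between diets in the fit without the block: limma called 0 of 15891 higher and 0 lower, with a smallest adjusted p of 0.263, while 2464 had an unadjusted p under 0.05. Chance gives 795 if transcripts are independent. Of the splits that mixed the diets, the highest (control sheep 1 with linseed sheep 1 and 2) gave 2345, the next 2227 and the lowest 56. With the sheep as a block, 4287 had an unadjusted p under 0.05 in limma. Exchanging the diets within sheep 2, within sheep 3 or within both gave 165, 588 and 106. The genes of smallest p with higher values under linseed were CCDC167 (log2 change 3.53 ± 0.67 SE), FUOM (2.90 ± 0.57), a fucose mutarotase, the cytokine MIF (3.25 ± 0.65), the potassium channel gene KCNK7 (2.61 ± 0.56), RETN (4.04 ± 0.87), which encodes resistin, CLEC3B (3.63 ± 0.80), the metalloproteinase inhibitor TIMP2 (3.10 ± 0.69) and TREM2 (3.73 ± 0.83), a lipid receptor of macrophages. MIF went from 84.9 ± 42.4 to 798.3 ± 342.4 RPKM (SD, n = 3) and TREM2 from 34.4 ± 42.2 to 279.5 ± 23.3. All 8 were higher in 3 of 3 sheep. Each had an adjusted p of 0.263 in limma without the block, and each passed with it, at 0.0401 to 0.0441.

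The genes of smallest p with lower values were CTH (-3.12 ± 0.64), which makes cysteine from cystathionine, ORMDL1 (-2.47 ± 0.53), a regulator of sphingolipid synthesis, the histone gene H1-6 (-2.69 ± 0.63), DCUN1D1 (-2.24 ± 0.53), RANBP6 (-2.19 ± 0.52), the histone chaperone gene RBBP4 (-3.35 ± 0.81), the surface protein gene CD24 (-2.44 ± 0.61) and the mitotic kinase gene WEE1 (-2.41 ± 0.61). CD24 went from 228.3 ± 83.4 to 39.9 ± 11.1 RPKM (SD, n = 3), and CTH from 12.7 ± 9.87 to 0.41 ± 0.54. All 8 were lower in 3 of 3 sheep, and each passed limma only with the block, at an adjusted p of 0.0401 to 0.0461.

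With the sheep as a block, limma called 203 transcripts higher and 213 lower with linseed, 90 and 121 genes of them with a symbol. All 416 moved alike in the 3 sheep, which a fit to differences within sheep favours, so this is not separate support for the calls. The same holds for the genes named above, picked by smallest p. The blocked calls lay close to the threshold, with a smallest adjusted p of 0.0401. The blocked fit called 0 with a pseudocount of 0.1, without the filter, at a mean of at least 5 RPKM, with median-of-ratios or quantile scaling, with voom on the recovered reads or with a length correction, and 253 higher and 1759 lower when milk proteins were left out of the total. Array weights without the block called 2919 higher and 2542 lower, with a weight of 25.6 on linseed sheep 2 and of 0.237 to 1.73 on the other libraries.

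Among lipid genes, stearoyl-CoA desaturase (SCD), which makes monounsaturated fatty acids, was lower with linseed in all 3 sheep, at 26.8 ± 12.1 RPKM in controls and 5.69 ± 3.01 with linseed (SD, n = 3; log2 change -2.09 ± 0.64 SE). Its adjusted p in limma was 0.263, and 0.0528 with the block. In the list of fatty acid synthesis and desaturation, 7 of 14 measured members were lower and 1 higher in all 3 sheep, with OXCT1 at -1.93 ± 0.68 and ATP citrate lyase (ACLY) at -1.65 ± 0.73. The desaturase genes FADS1 (-0.21 ± 0.50) and FADS2 (-0.34 ± 0.70) and acetyl-CoA carboxylase (ACACA, 0.61 ± 0.58) lay near their errors. After the length correction they had 0.09, -0.54 and 1.21, and the transcript of ACACA was 9422 nt long. The list had 0 calls over all transcripts and 0 adjusted over the list alone, or 0 and 3 with the block, and an adjusted p of 0.147 by camera.

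The list for triacylglycerol, the fat of milk, held genes that build, store or break it down. Of its 19 measured members, 9 were higher in all 3 sheep and 0 lower, with a median log2 change of 0.50. The median was -0.04 with milk proteins left out of the total, a scaling that moved the median of all tested transcripts from -0.12 to -0.52. Of the genes of fat breakdown, MGLL (1.70 ± 0.74 SE) and PNPLA2 (0.675 ± 0.58) were higher in all 3 sheep. LIPA (0.90 ± 0.88), LIPE (-0.24 ± 0.65) and ABHD5 (-0.47 ± 0.57) were not. The acyltransferase gene AGPAT2 went from 15.9 ± 6.17 to 80.7 ± 28.6 RPKM (SD, n = 3; log2 change 2.28 ± 0.62 SE) and passed limma with the block (adjusted p = 0.0457) but not without it (0.263). The seipin gene BSCL2 had a log2 change of 1.82 ± 0.55, GPAT4 1.33 ± 0.57, DGAT1 0.50 ± 0.56, GPAM -0.52 ± 0.59 and the lipid droplet coat gene PLIN2 -0.60 ± 0.60. The sign of DGAT1 turned when milk proteins were left out of the total (-0.09). Camera gave the list an adjusted p of 0.103, 0.0543 with the block and 0.898 with an estimated correlation, and after a length correction 0.0292 without the block and 0.0109 with it. The count was 0 over all transcripts and 0 adjusted over the list alone, or 1 and 3 with the block.

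Fatty acid uptake genes went both ways. The transporter gene SLC27A4 went from 2.43 ± 0.68 to 13.8 ± 1.92 RPKM (SD, n = 3), a log2 change of 2.12 ± 0.56 (SE). SLC27A4 passed limma with the block (adjusted p = 0.0455). Without the block its limma adjusted p was 0.263 over all transcripts and 0.0219 over the list alone, the latter not corrected for the number of lists. Lipoprotein lipase (LPL), which frees fatty acids from blood lipoproteins, had a log2 change of -1.40 ± 0.61. Of the 8 measured members, 2 were higher and 1 lower in all 3 sheep, and camera gave an adjusted p of 0.147. In the list of fatty acid oxidation and PPAR targets, 9 of 21 members were higher and 4 lower in all 3 sheep. The mitochondrial carrier gene UCP2 (2.68 ± 0.82, or ± 0.65 with the block) passed limma with the block (adjusted p = 0.0481). ETFB had 2.35 ± 0.67 and ECI1 1.86 ± 0.60, and camera gave the list an adjusted p of 0.103. The median of the list was 0.32, and -0.26 with milk proteins left out of the total. That list had 0 calls without the block, also adjusted over the list alone, and 1 and 8 with it.

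In the cholesterol synthesis list, 4 of 12 members were lower and 1 higher in all 3 sheep, and camera gave an adjusted p of 0.125. HMG-CoA synthase (HMGCS1), an early enzyme of the pathway, had a log2 change of -1.82 ± 0.64, and MSMO1 had -6.37, -3.54 and 1.28 in sheep 1, 2 and 3. The median of the list was -2.19, -0.67 and 0.18 in the 3 sheep. Among cholesterol efflux and LXR targets, SOAT1, which esterifies cholesterol, had -2.96 ± 1.05 (± 0.68 with the block). SOAT1 passed limma with the block (adjusted p = 0.0448), and the camera adjusted p of the list was 0.747. Of 6 lipid transcription factors, 2 were higher and 2 lower in all 3 sheep, with the liver X receptor gene NR1H3 at 1.32 ± 0.43, PPARG at 0.02 ± 0.78 and a camera adjusted p of 0.792, and the eicosanoid and lipid factor lists had medians of -0.40 and -0.23, opposite in sign to their camera directions. The eicosanoid list had the leukotriene receptor gene LTB4R at 1.63 ± 0.54, cyclooxygenase 2 (PTGS2) at -1.47 ± 0.65 and a camera adjusted p of 0.747. No member of these 4 lists passed without the block, also adjusted over the list alone, and with it the lists had 1, 2, 0 and 2 calls adjusted over the list alone in the order named.

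Of 22 antioxidant genes, 8 were higher and 4 lower in all 3 sheep. Glutathione peroxidase 1 (GPX1), which reduces peroxides, went from 581.4 ± 454 to 4183 ± 817 RPKM (SD, n = 3; log2 change 3.28 ± 0.78 SE) and passed limma with the block (adjusted p = 0.0441) and, without it, adjusted over the list alone (0.0302). The peroxiredoxin gene PRDX5 had 1.88 ± 0.64, whereas the superoxide dismutase gene SOD2 had -1.85 ± 0.74. Camera gave the list an adjusted p of 0.103, and its count adjusted over the list alone was 1 with and without the block.

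Immune cell markers went both ways within their lists. Of 16 macrophage genes, 6 were higher and 2 lower in all 3 sheep, with TREM2 and the complement gene C1QA (2.98 ± 0.95) above, and the mannose receptor gene MRC1 (-1.60 ± 0.78) and the integrin gene ITGAX (-0.61 ± 0.83) below. Lysozyme (LYZ) was lower in sheep 1 and 2 and higher in sheep 3 (-2.48, -3.76 and 1.29). TREM2 passed adjusted over the list alone (limma, 0.0139), and the camera adjusted p was 0.104. In the MHC class II list, the invariant chain gene CD74 had 2.86 ± 0.93 (± 0.70 with the block). CD74 passed limma with the block (adjusted p = 0.0485). Of 8 members of the list, 3 were higher in all 3 sheep (CD74, LY86 and CIITA) and 0 lower. The class II chain gene DQA changed by 3.06, -0.72 and 1.85 in sheep 1, 2 and 3. LY86, CD40, CD80, CD83 and CD86, also in this list, do not encode class II chains. Camera gave this list an adjusted p of 0.1 without the block and 0.0456 with it, and 0.875 with an estimated correlation and the block. The neutrophil genes S100A9 (2.28 ± 0.58) and S100A8 (1.85 ± 0.60), which encode calprotectin, were higher in 3 of 3 sheep; S100A9 passed adjusted over the list alone (limma, 0.0229), and the camera adjusted p of the 10 genes was 0.143.

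T and NK cell genes differed between sheep. Their median change was 0.89, -0.63 and -2.32 in sheep 1, 2 and 3, the camera adjusted p was 0.338, and CD247 of the T cell receptor complex had -2.06 ± 1.14. The interferon response list, with medians of 0.69, -0.13 and -1.19, had a camera adjusted p of 0.792 and an overall median of -0.26, opposite in sign to its camera direction. Among 17 inflammatory cytokine genes, interleukin 8 (CXCL8), which attracts neutrophils, had -2.65 ± 1.05 (± 0.595 with the block). CXCL8 passed limma with the block (adjusted p = 0.0441), going from 973.6 ± 1120 to 186.9 ± 248.3 RPKM (SD, n = 3). PTX3 had -2.08 ± 0.74, and the camera adjusted p of the list was 0.682. Of the B and plasma cell list only 4 genes were measured, too few to test, with CD79B at 1.31 ± 0.65. Adjusted over the list alone, limma without the block called 1 macrophage, 1 neutrophil, 0 MHC class II, 0 T and NK cell, 0 cytokine and 0 interferon genes, and with the block 5, 3, 2, 2, 3 and 0.

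On RPKM as deposited and without the block, ribosomal protein genes were the only list that passed camera. Of 61 measured members, 38 were higher and 1 lower in all 3 sheep, with a median log2 change of 0.98 and an adjusted p of 1.6e-10 by camera of limma. The adjusted p was 0.898 with an estimated correlation and 0.06 after quantile normalization. Splits of the libraries that mixed the diets gave 6 to 11 lists by camera at the preset correlation. The call of this list is therefore not by itself evidence of an effect of diet. The median was 2.11, 0.19 and 0.74 in sheep 1, 2 and 3, and the median of the fitted changes was 0.19 after quantile normalization and 0.36 with milk proteins left out of the total. No member passed, over all transcripts or adjusted over the list alone, with or without the block. RPL28 went from 67.8 ± 17.4 to 342.8 ± 229.6 RPKM (SD, n = 3) and RPL29 from 695.3 ± 358.9 to 3033 ± 1436. The members are short, with a median of 619 nt against 2297 nt for all tested transcripts, and after a length correction their median change was 0.38, with a camera adjusted p of 0.00157. They took 10.1% ± 4.51 of RPKM in controls and 16.7% ± 1.73 with linseed (exact permutation p = 0.1, the smallest 3 against 3 can give).

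Fold changes followed transcript length in all 3 sheep. Across transcripts, which are not independent replicates, the rank correlation of log2 change with length was -0.33 overall and -0.29, -0.14 and -0.36 in sheep 1, 2 and 3. The 3180 shortest transcripts, up to 1226 nt, had a median log2 change of 0.48, and the 3178 longest, from 4229 nt upward, one of -0.51. The 203 transcripts called higher with the block had a median length of 1066 nt and the 213 called lower one of 2585 nt. Among the genes named above, MIF (348 nt), RETN (330 nt) and FUOM (440 nt) were short, and DCUN1D1 (4752 nt) and RANBP6 (4621 nt) long. After the length correction their log2 changes were 2.46, 3.24, 2.17, -1.83 and -1.80.

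**Figure D2:**
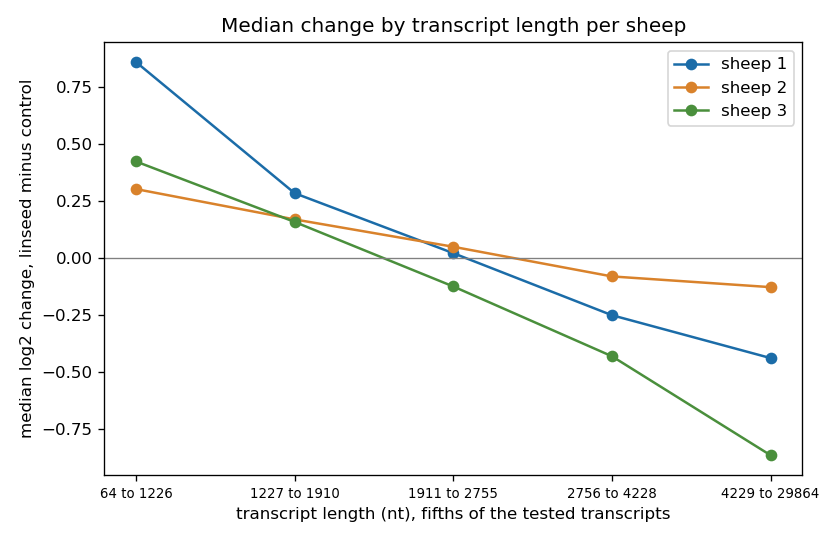
Median log2 change (linseed minus control, log2(RPKM + 1) scale) of the tested transcripts in 5 groups of transcript length (nt), with a line for each sheep. The median is lower in the longest group than in the shortest in all 3 sheep, going from 0.86 to -0.44 in sheep 1, 0.30 to -0.13 in sheep 2 and 0.42 to -0.87 in sheep 3.

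The remaining lists did not pass camera on RPKM as deposited without the block. Mammary epithelium genes differed between sheep, with medians of -0.04, 0.99 and -1.34, the adhesion molecule gene EPCAM at -1.82 ± 1.04, the keratin gene KRT8 at 1.76 ± 1.10 and a camera adjusted p of 0.951. Of 10 lactose synthesis genes, 3 were higher and 4 lower in all 3 sheep, with B4GALT1, the catalytic subunit of lactose synthase, at -2.04 ± 0.68 and hexokinase 2 (HK2) at -1.80 ± 0.70. The list had 0 calls adjusted over the list alone and 5 with the block, and a camera adjusted p of 0.682. The prolactin signalling list had an adjusted p of 0.342, with JAK2 at -1.47 ± 0.68. In the involution list TIMP1, a protease inhibitor, had 2.82 ± 0.78 (± 0.68 with the block). TIMP1 passed limma with the block (adjusted p = 0.0473) and, without it, adjusted over the list alone (0.0238). The median of the 6 genes was -0.53, opposite in sign to the camera direction (adjusted p = 0.839). Endoplasmic reticulum stress genes had an adjusted p of 0.147, with the chaperone gene HSPA5 at -1.75 ± 0.73 and medians of -1.75, -0.81 and 0.38 in the 3 sheep. Immediate early and heat shock genes, which handling can raise, had an adjusted p of 0.275 with a median of -0.80. Cell cycle genes had an adjusted p of 0.951, with PCNA at -1.85 ± 0.63. The 5 fibroblast, endothelial and myoepithelial genes had an adjusted p of 0.652, with TAGLN at 2.02 ± 0.94. Adjusted over this list alone, limma called 0 without the block and 1 with it. No erythrocyte or mitochondrially encoded gene entered the test, and these lists are not analysed here.

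**Figure D3:**
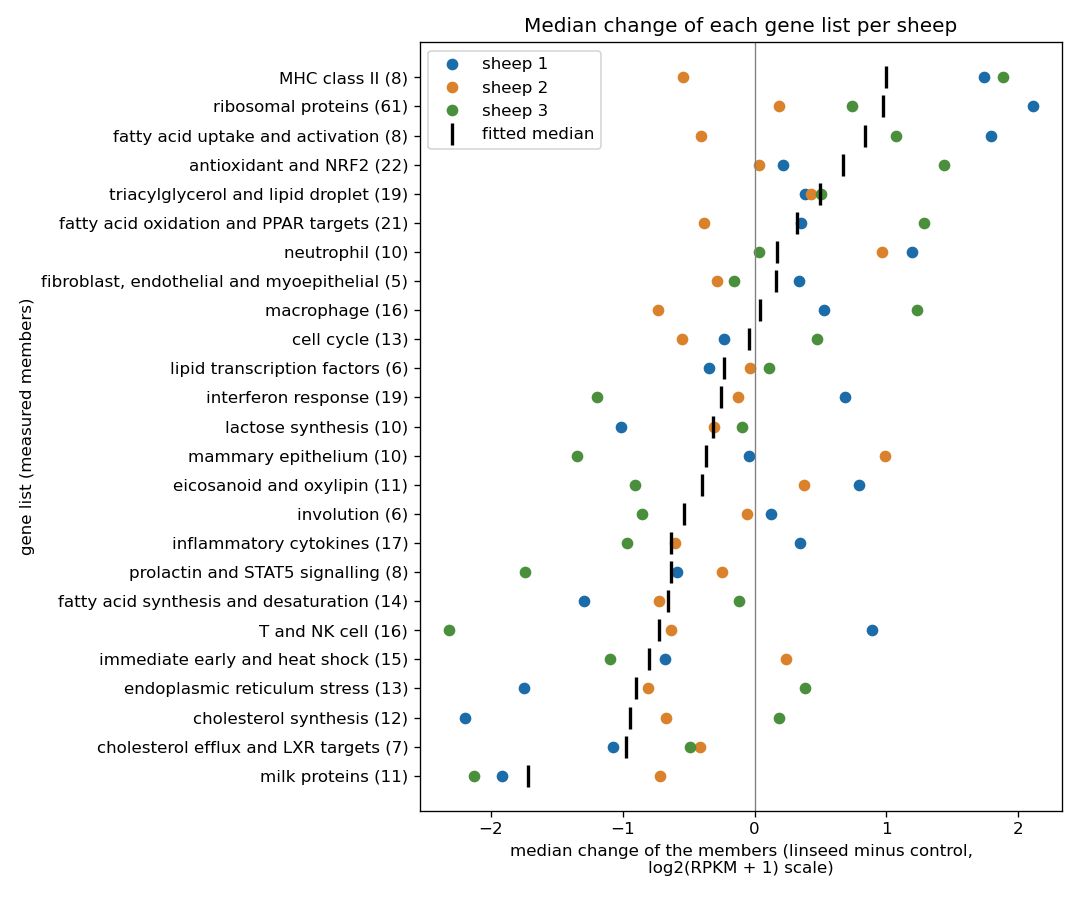
Median log2 change (linseed minus control, log2(RPKM + 1) scale) of the measured members of each tested list in sheep 1, 2 and 3 (coloured points), with the median of the fitted changes as a black bar and the number of members in brackets. Milk proteins lie below 0 and triacylglycerol genes above 0 in all 3 sheep (their fitted median is -0.04 with milk proteins left out of the total), while T and NK cell genes run from 0.89 in sheep 1 to -2.32 in sheep 3.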

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

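The count of 0 transcripts higher and 0 lower without the block was unchanged by other pseudocounts, no filter, a mean of at least 5 RPKM, the 3 other scalings, no trend, voom on the recovered reads, and leaving out each library or sheep in turn; at an unadjusted p under 0.05 limma had 2464, and with a library or sheep left out between 572 (without sheep 1) and 4628 (without sheep 3). Exceptions were array weights (2919 higher, 2542 lower), where linseed sheep 2 had a weight of 25.6, and the replicate block. The block gave 203 higher and 213 lower, and together with a pseudocount of 0.5 it gave 44 and 57, without the trend 355 and 268, and with milk proteins left out of the total 253 and 1759. That last scaling moved the median log2 change of all transcripts from -0.12 to -0.52, so the split shifts with it. Blocked fits without 1 sheep, which leave 1 residual degree of freedom, gave 107 higher and 145 lower without sheep 1, 96 and 77 without sheep 2, and 982 and 1018 without sheep 3. All other blocked settings gave 0 and 0. All settings with the block together with another choice, and voom and the length correction, were chosen after seeing the data. The cause of these differences was not tested. All 416 blocked calls kept their sign with voom and with the length correction, and 415 and 416 of them had an unadjusted p under 0.05 there. Both settings reuse the same 6 libraries, so this is not independent support. DESeq2, set aside for a table of raw counts, was not run on the RPKM table.

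Camera called 1 list, ribosomal proteins, in the fit without the block, and 0 after quantile normalization, with an estimated correlation, with fry's test of one direction, and with the estimated correlation and the block. Fry's test of change in either direction, which does not compare a list with other genes, gave an adjusted p of 0.0472 (limma) for 5 lists (fatty acid uptake, triacylglycerol, LXR targets, fatty acid oxidation, antioxidants). Camera called 2 lists with milk proteins left out of the total and 2 with the block, with MHC class II as the added list. The block changed no other list call. With the block, camera called 1 list without the filter. It called 2 with voom, with pseudocounts of 0.1 and 0.5, at a mean of at least 5 RPKM and with median-of-ratios scaling. It called 3 with milk proteins left out or without the trend, and 4 with quantile normalization or the length correction. Milk proteins were called lower in the last 4 of these and at a mean of at least 5 RPKM, triacylglycerol genes higher with the length correction, and endoplasmic reticulum stress genes lower with quantile normalization. MHC class II was not called in blocked fits without the filter, at a mean of at least 5 RPKM, or without sheep 1 or 3. Leaving out libraries or sheep gave 1 to 7 lists, and 2 to 7 with the block, and the ribosomal proteins were called in each of these. Milk proteins were called lower without control sheep 3, without linseed sheep 1 or 2, and without sheep 1 or 2. The cause was not tested. The milk protein share differed by -14.2 percentage points, by -13.7 with caseins, LALBA and PAEP alone, by -14.1 without the 10 most abundant other genes, and by -28.2 to -2.65 without 1 library.

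Of 136 named transcripts followed over 33 other settings, the log2 change of 15 changed sign in some setting, 14 of them from a change within its standard error. The other, the MHC class II gene DQA, went from 1.40 to -0.20 without control sheep 1 and to at most 2.58 (without control sheep 2). PAEP was among the 15: its change of 0.81 was -0.04 without control sheep 3 and -0.32 without linseed sheep 1. With the block 24 of the 136 passed. Of the tested transcripts, 574 had under 100 reads over the 6 libraries, and how far depth limits their calls was not tested.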

Other observations

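The tests of depth, of epithelial cell number and of macrophage number, and the exchange of diets within sheep, were chosen only after the results they bear on had been seen. Of 15891 tested transcripts, 7823 (49.2%) moved the same way in all 3 sheep, against 25% by chance for independent sheep. Of these, 3652 were higher and 4171 lower. The 25% assumes no shift shared by the sheep, whereas all 3 showed the trend with transcript length. Transcripts are also not independent, so the excess is not by itself evidence of a response to diet.

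Short transcripts were higher and long ones lower with linseed. A lower depth of the linseed libraries does not account for it: in sheep 3 the linseed library was the deeper one and the rank correlation of log2 change with length was -0.357, and with the reads of every library thinned to 4941935, sheep 1 and 2 had -0.294 and -0.135 against -0.292 and -0.137 at full depth, so that at least 98.5% was kept. Ribosomal protein genes alone do not account for it, since the correlation without them was -0.32. A bias of the libraries by transcript length stays open: in 946 genes with transcripts of different length, the longer had the lower change in 50.5% (95% exact interval 47.3% to 53.8%), but the lengths were so alike that the trend itself predicts a median difference of only -0.03. In the 149 genes whose longer transcript was at least 1.5 times as long, a restriction that the test as first written did not name and whose value was seen first, the share was 44.3% (36.2% to 52.7%) and the median difference 0.11 against -0.36 predicted; transcripts of 1 gene share reads, which may hide a difference, and a change with diet or with time of lactation was not tested.

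Caseins were lower with linseed while PAEP and LALBA were not. Fewer mammary epithelial cells as the whole cause would lower all of them alike, and PAEP exceeded the mean of the caseins by 4.79 and 3.04 on the log2 scale in sheep 1 and 2, where it was higher with linseed. In sheep 3 the difference was smaller, 0.88, and PAEP (-1.09), LALBA (-0.58) and the median of the mammary epithelium genes (-1.34) were lower together with the caseins, so fewer epithelial cells may account for part of the change there. The length trend predicts a difference of 0.13, against a mean of 2.90 ± 1.96 (SD, n = 3). A change in the epithelial cells with diet may remain as a hypothesis, but so does the later time of sampling, which the design cannot separate from diet.

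Macrophage markers moved apart. A larger number of macrophages as the whole cause would raise them alike. Of the 16 genes, 37.5% were higher in all 3 sheep, against 3652 of 15891 over all tested transcripts. Abundant members such as LYZ (-2.48 and -3.76) and CTSS (-1.72 and -2.42) were lower in sheep 1 and 2. Other abundant members were higher in sheep 1, 2 and 3: CD68 (2.37, 0.68 and 1.6), FCGR1A (2.32, 0.89 and 2.53) and AIF1 (3.73, 0.03 and 2.87). The test was written after the markers were seen to move apart, so it restates the pattern and cannot exclude a part played by macrophage number. In sheep 3 LYZ and CTSS were higher (1.29 and 1.25), so more macrophages may account for part of the change there. The length trend does not account for it: after the correction TREM2 had 3.46, from 3.73, and the SD of the members was 1.5, from 1.6. A change in the state of the macrophages, with diet or with time, may remain as a hypothesis and was not tested.

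The splits of the samples are too few to give a share under 0.05. Without the block, the real split and the highest of the other splits both gave 0 calls, so that all 10 of the 10 splits gave as many. With the sheep as a block the real assignment gave 416 calls and the highest of the other 3 exchanges 0, so that 1 of the 4 gave as many; for lists the real assignment gave 2 and the exchanges 11, 9 and 8. For gene lists without the block the real split gave 1 and the highest other 11, and all 10 of the 10 splits gave as many. Many more lists were called in splits that mix the diets, with and without the block, and the cause was not tested.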
